A study of Danio rerio with 15 samples.

How the data were processed

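The series measured gene expression in ventricles of adult zebrafish on whole-transcript arrays, with 250 ng of total RNA per array labelled with biotin. Per the labels each of the 15 arrays held RNA of 3 ventricles, with 3 such pools in each of 5 groups: control fish that went through the same baths without phenylhydrazine, fish at the end of 5 weeks of treatment, and fish 2, 5 and 9 days later. The deposited values are log2 expression values made by the authors with RMA in the R package oligo. RMA stands for robust multi-array average, which corrects background, normalises quantiles between arrays and summarises probes by median polish. Versions, the probe set level and the array annotation are not given in the sources used here. The values of all 75212 transcript clusters (the array's unit of about 1 gene) were read as deposited, and their ranges and near-equal quantiles were checked against a log2 scale.

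Transcript clusters were paired with gene symbols through an annotation table of the array. It held 21661 of the clusters, of which 20806 had exactly 1 symbol and 855 had several. Symbols were matched to the reference gene table of assembly GRCz12tu by gene ID for 20323 clusters, and 1 symbol was updated. Where a gene had several clusters (1365 genes) the one with the highest mean over all arrays was used. This left 19260 genes, 2317 of which have placeholder symbols and are not named in the text. The 53551 clusters without a symbol here and those with several were counted in a further fit. It held all 75212 clusters, named ones included, and adjusted over all of them.

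Differences were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 15 arrays and a moderated variance with an intensity trend, 2-sided. Adjusted p values follow Benjamini and Hochberg over all genes within each of 9 comparisons, with a threshold of 0.05, and an F test covered the 4 contrasts against control. The smallest p that an exact permutation of 3 against 3 arrays allows is 0.1, so calls rest on limma's model of the variance across genes. Gene lists for pathways, cell structures, cell types, blood content and technical checks, 33 in number, were tested with camera at a preset correlation of 0.01, as 297 tests in 1 Benjamini-Hochberg family, and again with an estimated correlation. Per list, genes were also counted after adjustment over the list alone. A list score is the median over the list's genes of an array's difference from the control mean. List scores were computed in R, and data preparation and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

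Sample groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes up to 10 genes with the largest rise and 10 with the largest fall against control. For recovery against the end of treatment it takes up to 5 and 5. It also takes up to 4 members of a described list with the smallest adjusted p. A few genes were chosen for the model (natriuretic peptides, myosin heavy chains, haemoglobins, hmox1a and pcna). After the values were seen, genes whose call is lost when 1 array is left out were left out of the text, except where the text gives that loss. Genes given for a difference between groups or for clock phase were also chosen after their values were seen.

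Alternatives were a 1.5-fold minimum, no variance trend, a robust variance, array weights, centring of arrays on their median, cyclic loess, leaving out the third of genes with the lowest mean, every transcript cluster, the mean of a gene's clusters, only the 6 arrays compared, the replicate number as a block, leaving out each array in turn, camera with an estimated correlation, and fry. A covariate for blood content, the median of 32 haemoglobin and erythroid genes per array, was added after seeing the data. Calls were compared with other splits of the arrays, 10 per pair of groups and 100 for all groups. Overlaps and later calls were compared with 100 simulations of unchanged groups.

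The method was tested on simulated data with the same number of arrays. Of 100 genes changed by 0.5 on the log2 scale 35% were recovered, and of 100 changed by 1 it was 93%. The mean fitted change was 1.01 for those changed upward by 1. A mitosis list shifted by 0.3 had a larger median fitted change, 0.37. There were 7 false calls among unchanged genes, and 0 false calls by limma in an unchanged group. The simulated genes were independent, so this does not test the correlation that camera assumes. The median standard error of a difference was 0.14 on the log2 scale. No detection values were used here, so a threshold of signal over background is unknown.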

Results

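Ventricles of adult zebrafish were profiled on 15 whole-transcript expression arrays. Phenylhydrazine, a compound that destroys red blood cells and so causes anaemia, was added to the water at intervals of 3 days over 5 weeks, each time for 30 min, at 1.25 µg/mL in the first week and 2.5 µg/mL afterwards. The series was set up to follow hearts that fail under this anaemia and then recover without the compound. There were 5 groups of 3 arrays: control fish, the end of treatment, and 2, 5 and 9 days after it. The labels give control fish no sampling day and no separate group for each recovery time. Recovery and sampling day therefore cannot be told apart in the comparisons below. Each array held the RNA of 3 pooled ventricles, and the number of arrays limits the precision. Median log2 signals lay between 4.022 and 4.095 on all 15 arrays.

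The first principal component held 32.2% of the variance and placed the groups at mean scores of -27 ± 2.4 for control, 34.1 ± 1.2 for the end of treatment, 7.9 ± 4.5 for 2 days, -1.6 ± 1.8 for 5 days and -13.4 ± 1.4 for 9 days (SD, n = 3). The second component held 11.6% and set 9 days apart, at -20.4 ± 7 against 5.6 ± 3.3 for control. Pearson correlations across transcript clusters, which are not independent replicates, were 0.989 to 0.993 between arrays of a group and 0.971 to 0.991 between groups. Among 19260 genes, 5189 (26.9%) differed between the 5 groups by limma's moderated F test.

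Every difference below is a log2 fold change ± its standard error from limma, with n = 3 arrays per group, and a gene is said to rise or fall where its adjusted p was under 0.05. Gene lists were compared with all other genes by camera, which called 158 of 297 tests at a preset correlation of 0.01. Random regroupings of the 15 arrays gave a median of 96 such calls and a highest of 145. Random groups can still hold unequal mixes of treated and control arrays, so the part due to the preset correlation is not known. With a correlation estimated from the data 32 calls held, against a highest of 4 in the regroupings, and the adjusted p with an estimated correlation is given beside each list.

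**Figure D1:**
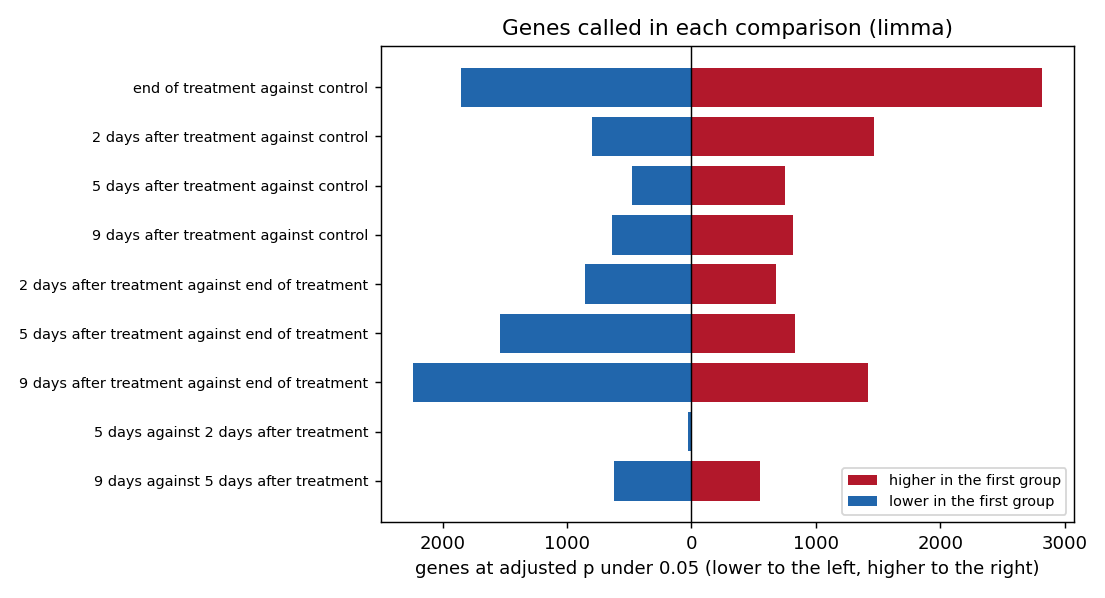
Number of genes called by limma in each of the 9 comparisons, with genes higher in the first-named group to the right and lower to the left. The end of treatment against control had the most, 2820 higher and 1849 lower, and 5 days against 2 days the fewest, 7 higher and 29 lower.

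The comparison of the end of treatment with control asks what the anaemic heart expressed. The glucose transporter genes slc2a3a and slc2a3b rose by 4.61 ± 0.24 (24.4-fold) and 3.58 ± 0.22 (11.9-fold). Other large rises were il11a, an interleukin 6 family cytokine (4.64 ± 0.39), the endoplasmic reticulum oxidase gene ero1a (4.30 ± 0.23), map1lc3cl, a relative of autophagy genes (6.47 ± 0.34), the vasodilator peptide gene adm2a (3.37 ± 0.28) and serpini1, a protease inhibitor (3.30 ± 0.17). The largest falls included sctr, the secretin receptor (-3.77 ± 0.26), the apolipoprotein gene apof (-2.87 ± 0.18), the troponin I gene tnni4b.3 (-2.66 ± 0.30), the kinase gene wnk4b (-2.49 ± 0.20) and hcn4, which encodes a pacemaker channel (-2.37 ± 0.12). The natriuretic peptide genes nppa and nppb, markers of cardiac stress, rose by 1.40 ± 0.09 (2.65-fold) and 2.21 ± 0.17 (4.64-fold), while npr3, their clearance receptor, fell by 2.07 ± 0.24. In all, 4669 genes changed, 2820 higher and 1849 lower, and 2305 of them by at least 1.5-fold. Testing every transcript cluster, named or not, gave 7042 calls.

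On the zebrafish assembly GRCz12tu, slc2a3a (transcript cluster 13073269) lies on chromosome 19 from 10779743 to 10806998 and il11a (13030428) on chromosome 16 from 12962017 to 12970048. The gene hcn4 (13061256) lies on chromosome 18 from 1620347 to 1761018 and sctr (13263837) on chromosome 9 from 900521 to 926113. The genes nppb (13248786) and nppa (13248793) are neighbours on chromosome 8, from 58368540 to 58369564 and from 58372053 to 58376685.

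Genes of the response to low oxygen and of sugar breakdown were mostly higher at the end of treatment. Of 32 hypoxia response genes 20 rose and 2 fell (20 and 4 adjusted over the list alone), among them egln3, an oxygen-sensing hydroxylase (2.68 ± 0.20), ndrg1a (2.05 ± 0.14) and the vascular growth factor gene vegfab (1.15 ± 0.10). The list had adjusted p = 0.0666 with an estimated correlation. Of 32 glycolysis genes 21 rose and 4 fell, the same numbers adjusted over the list alone, with eno1b at 3.04 ± 0.23, pfklb at 1.84 ± 0.13 and gapdhs at 1.73 ± 0.10 (adjusted p = 0.0722 with an estimated correlation). In fatty acid oxidation 7 of 43 genes rose and 14 fell (8 and 17 adjusted over the list alone). The lipoprotein lipase gene lpla fell by 1.42 ± 0.14, whereas the pyruvate dehydrogenase kinase genes pdk2b and pdk2a rose by 3.00 ± 0.35 and 1.05 ± 0.11. This list's median was -0.11, its mean was 0.00 and its test pointed down, with adjusted p = 0.522 with an estimated correlation. Its call at the preset correlation was lost without control replicate 3 (adjusted p = 0.0798) and without end of treatment replicate 3 (adjusted p = 0.108). Of 30 tricarboxylic acid cycle genes 12 fell and 4 rose (14 and 4 adjusted over the list alone; adjusted p = 0.288 with an estimated correlation). Of 87 oxidative phosphorylation genes 17 fell and 11 rose (21 and 11 adjusted over the list alone; adjusted p = 0.622 with an estimated correlation).

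Cell division genes rose together. Of 45 mitosis genes 39 rose and 0 fell (limma, 42 and 0 adjusted over the list alone), including cdk1 (1.85 ± 0.14), nusap1 (2.13 ± 0.19) and kif20a (1.66 ± 0.16), and the list held with an estimated correlation (adjusted p = 0.00362). Of 51 DNA replication genes 36 rose and 0 fell (41 and 0 adjusted over the list alone; adjusted p = 0.0238 with an estimated correlation). Examples were tk1, a thymidine kinase (2.58 ± 0.16), the chromatin assembly gene chaf1a (2.01 ± 0.14) and the replication clamp gene pcna (1.57 ± 0.11, 2.96-fold). Of 44 proteasome genes 21 rose and 0 fell (24 and 0 adjusted over the list alone), with psma3 at 0.63 ± 0.08 and psmb2 at 0.62 ± 0.10 (adjusted p = 0.158 with an estimated correlation).

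Many macrophage, pan leukocyte and inflammation genes rose at the end of treatment. Of 31 macrophage genes 18 rose and 0 fell (20 and 0 adjusted over the list alone), led by mpeg1.2 (1.74 ± 0.13), mpeg1.1 (2.12 ± 0.19) and the growth factor receptor gene csf1ra (1.46 ± 0.14). The macrophage list held with an estimated correlation (adjusted p = 0.0242), as did the inflammation list (adjusted p = 0.0145). In the latter 21 of 54 genes rose and 0 fell, the same adjusted over the list alone, among them ptgs2b, a prostaglandin synthase gene (2.87 ± 0.30), socs3b, a cytokine signalling inhibitor (2.06 ± 0.20), and the complement gene c7a (1.59 ± 0.13). Of 19 pan leukocyte genes 18 rose and 0 fell, also adjusted over the list alone, with itgb2 at 1.43 ± 0.11 and spi1b at 1.47 ± 0.14 (adjusted p = 0.0889 with an estimated correlation). Neutrophil genes rose in 6 and fell in 1 of 21 (7 and 1 adjusted over the list alone; adjusted p = 0.347 with an estimated correlation), and lymphocyte genes rose in 4 and fell in 1 of 33 (3 and 1 adjusted over the list alone), a list that was not called. Of 42 interferon response genes 13 rose and 1 fell (17 and 1 adjusted over the list alone), including tap2a (1.44 ± 0.19; adjusted p = 0.29 with an estimated correlation for the list).

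Several genes of red blood cells rose at the end of treatment. The adult globin genes hbaa2 and hbba2 rose by 2.36 ± 0.28 (5.14-fold) and 1.96 ± 0.20 (3.89-fold). The other 4 measured genes of the haemoglobin list, hbae1.1, hbae3, hbbe2 and hbbe3, did not pass the test. Their control means were low, at 5.14, 3.94, 4.49 and 3.61, against 8.23 and 8.33 for hbaa2 and hbba2. Of 26 erythroid maturation genes 15 rose and 6 fell, the same adjusted over the list alone (adjusted p = 0.433 with an estimated correlation). The band 3 anion exchanger gene slc4a1a rose by 2.17 ± 0.20 and the haem synthesis gene urod by 1.42 ± 0.13. Of 14 thrombocyte genes 7 rose and 3 fell (8 and 3 adjusted over the list alone), a list that was not called. In the list for oxidative stress, haem and iron 18 of 51 rose and 1 fell (19 and 1 adjusted over the list alone; adjusted p = 0.117 with an estimated correlation), with the biliverdin reductase gene blvra at 1.35 ± 0.09. The haem oxygenase gene hmox1a differed by -0.14 ± 0.18 and did not pass the test. With a blood score of each array as a covariate, 1963 genes were called between the end of treatment and control. This fit was chosen after seeing the data, and at equal residual variance it multiplied the standard error by 1.53.

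Genes of the contractile apparatus and of ion handling were lower. Of 28 sarcomere genes 14 fell and 1 rose (17 and 1 adjusted over the list alone), with the Z-disc gene ldb3a at -0.60 ± 0.07 and mybpc3 at -0.39 ± 0.06. The myosin light chain gene myl4 fell by 0.98 ± 0.13, but its signal was low, with means of 4.43 in control and 3.44 at the end of treatment. Of 23 calcium handling and ion channel genes 13 fell and 4 rose (14 and 5 adjusted over the list alone), among them the sodium and calcium exchanger gene slc8a1a (-0.85 ± 0.07), jph2 (-0.87 ± 0.08) and the calcium channel gene cacna1c (-0.84 ± 0.09). Both lists held with an estimated correlation, with adjusted p = 0.0458 and adjusted p = 0.0274. The myosin heavy chain gene myh6 differed by -0.78 ± 0.28 with adjusted p = 0.0521. Its relative myh7 differed by 0.42 ± 0.32 with adjusted p = 0.396, and by -0.55 when its transcript clusters were averaged. The cardiac stress list had 7 genes higher and 9 lower of 24 (7 and 11 adjusted over the list alone), a median of -0.14, a mean of 0.23 and a test that pointed down, and was not called. In this list nppal, a natriuretic peptide relative, rose by 4.09 ± 0.53, at 6.41 on end of treatment replicate 1 and 9.30 and 9.60 on the others, and its rise was 5.10 without that array.

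Some vessel and matrix genes changed as well. Of 43 endothelial genes 23 rose and 2 fell, the same adjusted over the list alone, with esm1 at 2.93 ± 0.23, the Notch ligand gene dll4 at 1.51 ± 0.14 and sox18 at 0.99 ± 0.09 (adjusted p = 0.07 with an estimated correlation). Of 82 extracellular matrix genes 22 rose and 4 fell (23 and 5 adjusted over the list alone), led by the collagen-modifying enzyme genes plod2 (2.61 ± 0.13), plod1a (2.06 ± 0.13) and loxl2a (2.95 ± 0.27; adjusted p = 0.338 with an estimated correlation for the list). Of 46 heart regeneration genes 17 rose and 10 fell (18 and 10 adjusted over the list alone), with hapln1b at 1.27 ± 0.17, the growth factor gene mdka at 1.12 ± 0.16 and the transcription factor gene tbx20 at -0.73 ± 0.09, and that list was not called. The epicardium list had 4 of 19 genes higher and 6 lower, also adjusted over the list alone, and was not called, with a median of -0.06 and a mean of 0.01 (its test pointed down). Smooth muscle genes rose in 3 and fell in 2 of 22, skeletal muscle genes rose in 1 and fell in 4 of 30, and neither list was called.

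The comparison of 2 days after treatment with control shows what differed early in recovery. Globin and other red cell genes had some of the largest rises: hbaa2 by 2.99 ± 0.28 (7.94-fold), slc4a1a by 2.88 ± 0.20 (7.36-fold) and hbba2 by 2.56 ± 0.20 (5.88-fold). Other large rises were the thymidylate synthase gene tyms (2.46 ± 0.16), tk1 (2.43 ± 0.16), the endothelin gene edn1 (2.66 ± 0.17), the chaperone gene hspa8b (3.34 ± 0.48), the tropomodulin gene tmod4 (2.75 ± 0.19) and map1lc3cl (3.73 ± 0.34). The genes avpr1ab, a vasopressin receptor (-1.97 ± 0.21), the transcription factor gene klf4 (-1.83 ± 0.17), the hedgehog ligand gene dhh (-1.74 ± 0.24), the muscarinic receptor gene chrm2a (-1.50 ± 0.24) and sema3aa (-1.50 ± 0.18) were among the largest falls. In all, 2268 genes changed, 1468 higher and 800 lower, 1028 of them by at least 1.5-fold. The count was 1469 without control replicate 1 and 1488 without 2 days after treatment replicate 3. With the blood score as a covariate, limma called 0 genes (1512 at an unadjusted p under 0.05). That fit, however, multiplied the standard error by 2.6 at equal residual variance.

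Of 26 erythroid maturation genes 19 rose and 0 fell at 2 days (20 and 0 adjusted over the list alone), and the list held with an estimated correlation (adjusted p = 0.0327). Thrombocyte genes rose in 9 of 14, with tubb1 at 2.42 ± 0.23 (10 higher and 1 lower adjusted over the list alone; adjusted p = 0.062 with an estimated correlation). Mitosis genes rose in 28 of 45 (40 adjusted over the list alone) and DNA replication genes in 35 of 51 (41 adjusted over the list alone), with pcna at 1.64 ± 0.11. Macrophage genes rose in 13 of 31 (13 higher and 1 lower adjusted over the list alone), with mpeg1.2 at 2.18 ± 0.13. These 3 lists held with an estimated correlation, with adjusted p = 0.00325, adjusted p = 0.00704 and adjusted p = 0.0238. Sarcomere genes fell in 7 of 28 (13 adjusted over the list alone), including the titin genes ttn.1 (-1.01 ± 0.18) and ttn.2 (-1.03 ± 0.18), and ion handling genes fell in 11 and rose in 2 of 23 (13 and 2 adjusted over the list alone), with hcn4 at -1.33 ± 0.12. Both held with an estimated correlation, at adjusted p = 0.0376 and adjusted p = 0.0238. Interferon response genes rose in 19 of 42 (22 adjusted over the list alone), including isg15 (1.54 ± 0.20) and dhx58 (1.37 ± 0.15), with adjusted p = 0.11 with an estimated correlation. Hypoxia response genes rose in 10 of 32 (11 higher and 1 lower adjusted over the list alone; adjusted p = 0.252 with an estimated correlation), and with the blood score as a covariate the list's median turned from 0.21 to -0.004. Of 32 glycolysis genes 8 rose and 2 fell (9 and 5 adjusted over the list alone), and the list was not called. Pan leukocyte genes rose in 15 of 19 (16 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation), and nppa and nppb were still higher, by 0.80 ± 0.09 and 1.67 ± 0.17.

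At 5 days after treatment against control, the largest rises included prc1b (2.72 ± 0.25), map1lc3cl (2.70 ± 0.34), tyms (2.58 ± 0.17), tk1 (2.41 ± 0.16), nusap1 (2.35 ± 0.19), the ribonucleotide reductase gene rrm2l (2.31 ± 0.33), kif20a (2.19 ± 0.16) and cdk1 (2.07 ± 0.14, 4.21-fold). The globin gene hbaa2 rose by 2.31 ± 0.28 (4.94-fold). Falls included the cytochrome gene cyp2ad2 (-1.96 ± 0.24), the transcription factor gene klf11b (-1.60 ± 0.21), the kinase gene alpk2 (-1.43 ± 0.24) and avpr1ab (-1.28 ± 0.21). In all, 1227 genes changed, 752 higher and 475 lower, 567 of them by at least 1.5-fold. The count was 762 without control replicate 1, 755 without control replicate 3, 757 without 5 days after treatment replicate 2, and 777 in a fit of the 6 arrays compared. With the blood score as a covariate 9 genes were called and, at equal residual variance, the standard error was multiplied by 1.99.

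Mitosis genes rose in 34 of 45 at 5 days (43 adjusted over the list alone; adjusted p = 0.00083 with an estimated correlation) and DNA replication genes in 16 of 51 (28 adjusted over the list alone; adjusted p = 0.0238 with an estimated correlation), with pcna at 1.2 ± 0.11. Macrophage genes rose in 12 of 31 (21 adjusted over the list alone; adjusted p = 0.0121 with an estimated correlation). Ion handling genes fell in 4 of 23 (7 adjusted over the list alone; adjusted p = 0.0287 with an estimated correlation), with hcn4 at -1.11 ± 0.12 and jph1a at -0.63 ± 0.07. Erythroid maturation genes rose in 13 of 26 (17 adjusted over the list alone), among them the haem synthesis gene alas2 (1.60 ± 0.17; adjusted p = 0.0857 with an estimated correlation for the list). Pan leukocyte genes rose in 12 of 19 (16 adjusted over the list alone; adjusted p = 0.0933 with an estimated correlation). Of 32 hypoxia response genes 6 rose, also adjusted over the list alone, and of 32 glycolysis genes 2 rose and 1 fell, again the same over the list alone, and neither list was called. The glycolysis median turned from 0.002 to -0.115 with the blood score as a covariate (adjusted p = 0.0162). The genes nppa and nppb rose by 0.63 ± 0.09 and 1.02 ± 0.17. The gene myh7 was higher by 1.14 ± 0.32 (adjusted p = 0.0405) and myh6 lower, at -1.03 ± 0.28 (adjusted p = 0.0374). The myh7 call was lost without control replicate 1, 2 or 3 (adjusted p = 0.129, 0.06 and 0.0967) and without 5 days after treatment replicate 1 or 2 (0.0936 and 0.162). The myh6 call was lost without control replicate 1, 2 or 3 (0.0902, 0.0692 and 0.108) and without 5 days after treatment replicate 2 or 3 (0.0536 and 0.0601), and whether probes distinguish the pair was not tested.

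At 9 days after treatment against control, the mitosis list was not called and other genes stood out. The largest rises included the chloride channel family gene clic5a (2.49 ± 0.14, 5.61-fold), angptl4, an inhibitor of lipoprotein lipase (2.30 ± 0.36), the stress gene ddit4 (2.11 ± 0.38), lonrf1 (1.82 ± 0.28), map1lc3cl (3.07 ± 0.34) and the granulin gene grna.1 (2.79 ± 0.46), though whether its probes distinguish it from its relative grna.2 was not tested. Falls included cyp2ad2 (-1.72 ± 0.24), the glutamate receptor gene grin2da (-1.48 ± 0.13), klf4 (-1.45 ± 0.17), the smooth muscle gene cnn1b (-1.26 ± 0.22), pcdh19 (-1.24 ± 0.14) and the chaperone gene hsp90aa1.1 (-1.21 ± 0.25). In all, 1452 genes changed, 816 higher and 636 lower, 568 of them by at least 1.5-fold. The count was 890 without control replicate 1, 920 without control replicate 2 and 713 without 9 days after treatment replicate 3. With the blood score as a covariate it was 439, and at equal residual variance the standard error was multiplied by 1.36.

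Of 45 mitosis genes 1 rose and 0 fell at 9 days by limma (0 and 0 adjusted over the list alone), pcna differed by 0.05 ± 0.11 with adjusted p = 0.844. The mitosis gene that rose, mastl, lost its call without control replicate 1 or 3 (adjusted p = 0.175 and 0.1) and without 9 days after treatment replicate 2 or 3 (0.151 and 0.12). Macrophage genes rose in 14 of 31 (17 adjusted over the list alone), with mpeg1.1 at 1.53 ± 0.19, and inflammation genes rose in 9 of 54 (13 adjusted over the list alone), with c7a at 0.88 ± 0.13 and stat3 at 0.43 ± 0.09. These lists held with an estimated correlation, at adjusted p = 0.0152 and adjusted p = 0.0238. Pan leukocyte genes rose in 11 of 19 (15 adjusted over the list alone; adjusted p = 0.0956 with an estimated correlation). Proteasome genes fell in 8 and rose in 1 of 44 (21 and 2 adjusted over the list alone), with psmd11b at -0.51 ± 0.09 (adjusted p = 0.11 with an estimated correlation). Erythroid maturation genes rose in 9 of 26 (9 higher and 1 lower adjusted over the list alone; adjusted p = 0.303 with an estimated correlation), and hbaa2 rose by 1.39 ± 0.28 (2.62-fold). Ion handling genes fell in 5 of 23 (6 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation), with hcn4 at -1.08 ± 0.12. Hypoxia response genes rose in 7 and fell in 1 of 32 (11 and 1 adjusted over the list alone; adjusted p = 0.331 with an estimated correlation), the mitophagy gene bnip3 by 1.15 ± 0.19. The gene nppa rose by 0.43 ± 0.09, and nppb differed by 0.30 ± 0.17 with adjusted p = 0.331.

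**Figure D2:**
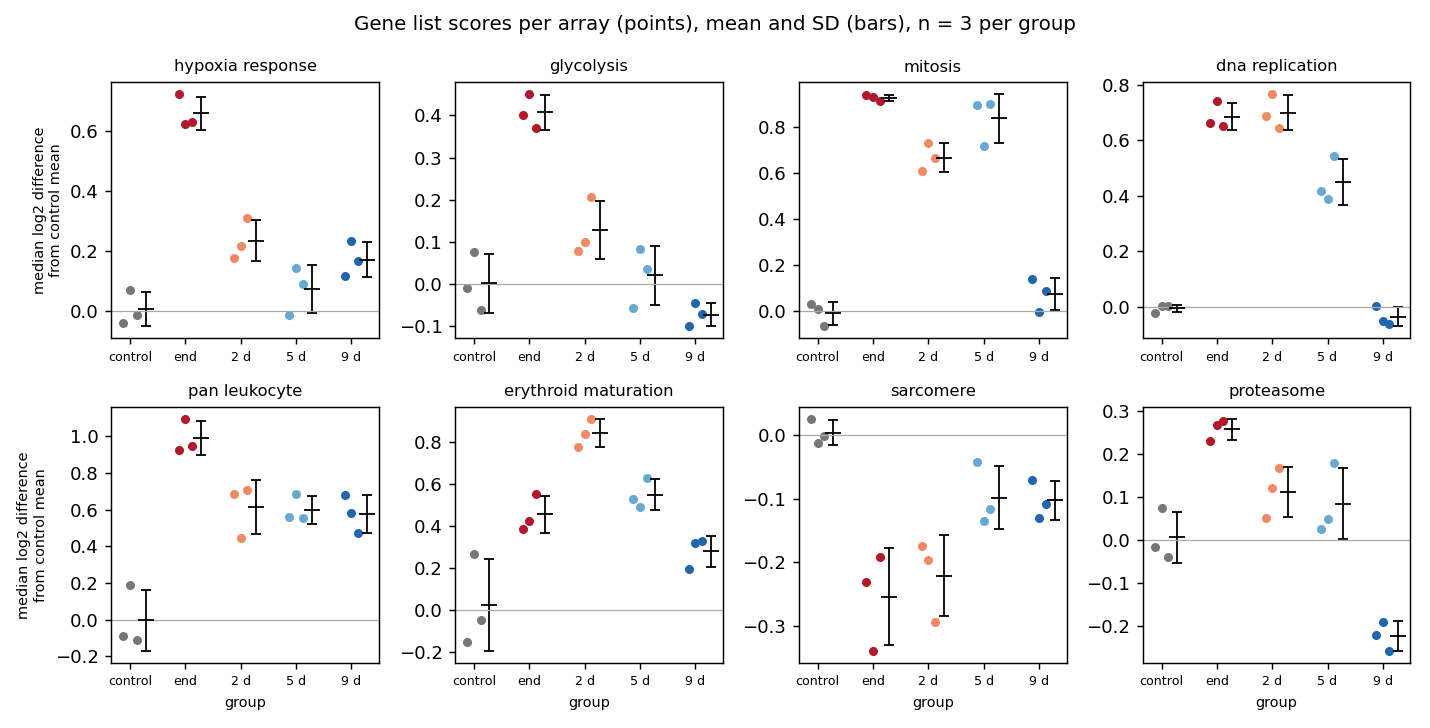
Score of 8 gene lists on each array, as the median log2 difference of the list's genes from the control mean (points), with mean and SD (bars), n = 3 per group. Mean mitosis scores were 0.93, 0.67 and 0.84 at the end of treatment, 2 and 5 days and 0.07 at 9 days, while mean pan leukocyte scores were 0.99 at the end of treatment and 0.61, 0.60 and 0.58 at 2, 5 and 9 days.

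The comparisons of recovery times with the end of treatment ask which levels moved once the compound was withdrawn. Within 2 days slc2a3a fell by 3.35 ± 0.24 (10.2-fold lower), il11a by 2.93 ± 0.39, map1lc3cl by 2.74 ± 0.34 and nppal by 2.69 ± 0.53. At 2 days il11a was 5.13 and 5.27 on replicates 1 and 2 and 7.34 on replicate 3, and it fell by 3.65 without replicate 3, while nppal fell by 3.71 without end of treatment replicate 1. The genes sctr (2.86 ± 0.26, 7.25-fold), hsp90aa1.1 (2.19 ± 0.25), hspa8b (2.29 ± 0.48), hif1al2 (2.01 ± 0.29) and the stress transcription factor gene atf3 (1.99 ± 0.29) rose. Of 32 glycolysis genes 19 fell and 0 rose (21 lower and 1 higher adjusted over the list alone), and of 54 inflammation genes 10 fell and 0 rose (11 and 0 adjusted over the list alone) by limma. These lists held with an estimated correlation, at adjusted p = 0.0238 and adjusted p = 0.00704. Hypoxia response genes fell in 15 and rose in 2 of 32 (17 and 3 adjusted over the list alone; adjusted p = 0.0563 with an estimated correlation), including ndrg1a (-1.44 ± 0.14) and vegfab (-1.04 ± 0.10). Erythroid maturation genes rose in 18 and fell in 1 of 26 (18 and 2 adjusted over the list alone), with the transcription factor gene klf1 at 1.45 ± 0.17 and the erythropoietin receptor gene epor at 1.36 ± 0.20 (adjusted p = 0.081 with an estimated correlation for the list). The gene nppa fell by 0.60 ± 0.09. In all, 1536 genes changed, 678 higher and 858 lower, 754 of them by at least 1.5-fold, and 984 were called without 2 days after treatment replicate 1. With the blood score as a covariate 514 were called, and at equal residual variance the standard error was multiplied by 1.59.

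By 5 days against the end of treatment, il11a had fallen by 4.13 ± 0.39 (17.5-fold lower), slc2a3a by 3.78 ± 0.24 (13.7-fold lower), nppal by 3.67 ± 0.53 (it fell by 4.68 without end of treatment replicate 1) and pdk2b by 3.43 ± 0.35. The genes sctr (3.12 ± 0.26), apof (2.27 ± 0.18), tnni4b.3 (2.08 ± 0.30) and wnk4b (1.84 ± 0.20) had risen. Glycolysis genes fell in 21 and rose in 1 of 32 (21 and 2 adjusted over the list alone), hypoxia response genes fell in 17 and rose in 2 of 32 (18 and 3 adjusted over the list alone), and inflammation genes fell in 19 of 54 (20 adjusted over the list alone). These lists held with an estimated correlation, at adjusted p = 0.0238, adjusted p = 0.0446 and adjusted p = 0.0118. Mitosis genes rose in 2 and fell in 1 of 45 (1 and 1 adjusted over the list alone), and that list was not called. The genes nppa and nppb fell by 0.78 ± 0.09 and 1.2 ± 0.17. In all, 2377 genes changed, 835 higher and 1542 lower, 1079 of them by at least 1.5-fold.

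By 9 days against the end of treatment, slc2a3a had fallen by 4.25 ± 0.24 (18.99-fold lower), ero1a by 4.2 ± 0.23 (18.4-fold lower), il11a by 4.17 ± 0.39 and nppb by 1.92 ± 0.17. The genes sctr (3.32 ± 0.26, 9.98-fold), sult2st1 (2.23 ± 0.16), tnni4b.3 (2.18 ± 0.30) and apof (2.07 ± 0.18) had risen. Cell division genes were lower: of 45 mitosis genes 36 fell (41 adjusted over the list alone) and of 51 DNA replication genes 37 fell (43 adjusted over the list alone), including tyms (-2.81 ± 0.17) and cdk1 (-1.76 ± 0.14). Of 44 proteasome genes 33 fell (39 adjusted over the list alone), with psma3 at -0.82 ± 0.08, and of 32 glycolysis genes 22 fell and 4 rose, also adjusted over the list alone. These 4 lists held with an estimated correlation, at adjusted p = 0.00325, adjusted p = 0.0116, adjusted p = 0.0238 and adjusted p = 0.0274. Sarcomere genes rose in 8 and fell in 1 of 28 (9 and 1 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation) and ion handling genes rose in 12 and fell in 3 of 23 (13 and 4 adjusted over the list alone; adjusted p = 0.0632 with an estimated correlation), with hcn4 at 1.29 ± 0.12. In all, 3662 genes changed, 1421 higher and 2241 lower, 1634 of them by at least 1.5-fold.

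Between 2 and 5 days after treatment few genes changed. Of 45 mitosis genes 1 rose and 0 fell by limma (9 and 0 adjusted over the list alone), namely cdc20, a regulator of anaphase (0.92 ± 0.14), and the list's median rise of 0.16 held with an estimated correlation (adjusted p = 0.0458). Of 51 DNA replication genes 1 fell and 0 rose (15 and 0 adjusted over the list alone), namely mcm7 (-0.63 ± 0.11), with a list median of -0.31 (adjusted p = 0.0241 with an estimated correlation). Erythroid maturation genes fell in 1 of 26 (15 adjusted over the list alone), namely uros (-0.50 ± 0.08), with a list median of -0.41 and adjusted p = 0.069 with an estimated correlation. In all, 36 genes changed, 7 higher and 29 lower. The count was 18, 8 and 18 without 2 days after treatment replicate 1, 2 or 3, and 10 and 22 without 5 days after treatment replicate 2 or 3. It was 15 without the variance trend, 5 when every transcript cluster was tested and 3 with the blood score as a covariate. The gene cdc20 lost its call without 2 days after treatment replicate 1 or 2 (adjusted p = 0.0593 and 0.0527) or 5 days after treatment replicate 2 (0.0733). Without 2 days after treatment replicate 1, 2 or 3 the adjusted p of mcm7 was 0.0764, 0.093 and 0.0779 and that of uros 0.0616, 0.0601 and 0.0779. Without 5 days after treatment replicate 2 they were 0.115 and 0.0851, and without 5 days after treatment replicate 1 that of mcm7 was 0.0801. When adjusted over the 33 lists of this comparison alone, 0 lists were called by camera with an estimated correlation and 15 with the preset correlation.

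Between 5 and 9 days the cell division genes fell. Of 45 mitosis genes 30 fell and 0 rose by limma (39 and 0 adjusted over the list alone), led by cdk1 (-1.98 ± 0.14), cdc20 (-2 ± 0.14) and kif20a (-1.99 ± 0.16), and of 51 DNA replication genes 23 fell (31 adjusted over the list alone), led by tyms (-3.02 ± 0.17) and tk1 (-2.41 ± 0.16). Proteasome genes fell in 13 of 44 (27 adjusted over the list alone), with psmd2 at -0.41 ± 0.06. The 3 lists held with an estimated correlation, at adjusted p = 0.00083, adjusted p = 0.0116 and adjusted p = 0.0458, and 2 lists did when adjusted over the 33 lists of this comparison alone. Of 40 apoptosis and p53 genes 13 rose and 0 fell (15 and 0 adjusted over the list alone), including the cell cycle inhibitor gene cdkn1bb (0.92 ± 0.13) and bnip3 (1.2 ± 0.19), with adjusted p = 0.163 with an estimated correlation. Over the same interval 0 of 19 pan leukocyte genes and 0 of 31 macrophage genes changed by limma, and neither list was called. Over all genes 3592 had an unadjusted p under 0.05 and 1178 changed, 552 higher and 626 lower, 485 of them by at least 1.5-fold. The count was 615 without 5 days after treatment replicate 3, 664 without 9 days after treatment replicate 3, and 636 in a fit of the 6 arrays compared. With the blood score as a covariate it was 344, and at equal residual variance the standard error was multiplied by 1.28.

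Of the 4669 genes changed at the end of treatment, 1216 (26%) moved back towards control by 2 days, 1930 (41.3%) by 5 days and 2535 (54.3%) by 9 days, in the sense of a call in the opposite direction against the end of treatment. Still called against control in the original direction were 1825 (39.1%), 998 (21.4%) and 869 (18.6%). Genes simulated to stay at the end of treatment level gave 0 moved back in 100 simulations. Genes simulated at the control level gave medians of 4106.5, 4153.5 and 4132 moved back and 0 still called by limma. In each simulation all genes of the recovery group were redrawn around the observed level, so few calls against that level could pass the adjustment. The 0 counts are therefore no benchmark for the real counts. The contrasts against the end of treatment and against control also share arrays with the call that selected the genes. The genes slc2a3a and il11a moved back at 2, 5 and 9 days and were not called against control at 5 and 9 days. The genes nppa and hcn4 also moved back at all 3 times and were still called against control at each of them.

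The comparisons with control shared many calls in the same direction. Calls at 2 and 5 days shared 956 genes in the same direction and 0 in opposite directions, by limma, and calls at 5 and 9 days shared 432 and 11. The end of treatment shared 13, 7 and 56 genes in opposite directions with 2, 5 and 9 days, and 2 and 9 days shared 606 in the same direction and 16 in opposite ones. Independent calls would have given 57.3 shared higher and 19.7 shared lower at 2 and 5 days. Simulated unchanged groups against the real control arrays gave 0. Every gene was unchanged in those simulations, so few calls could pass the adjustment and the 0 is no benchmark. The 3 control arrays are too few to be divided into separate sets with replicates. The part of the sharing that comes from the common control arrays is therefore not known.

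**Figure D3:**
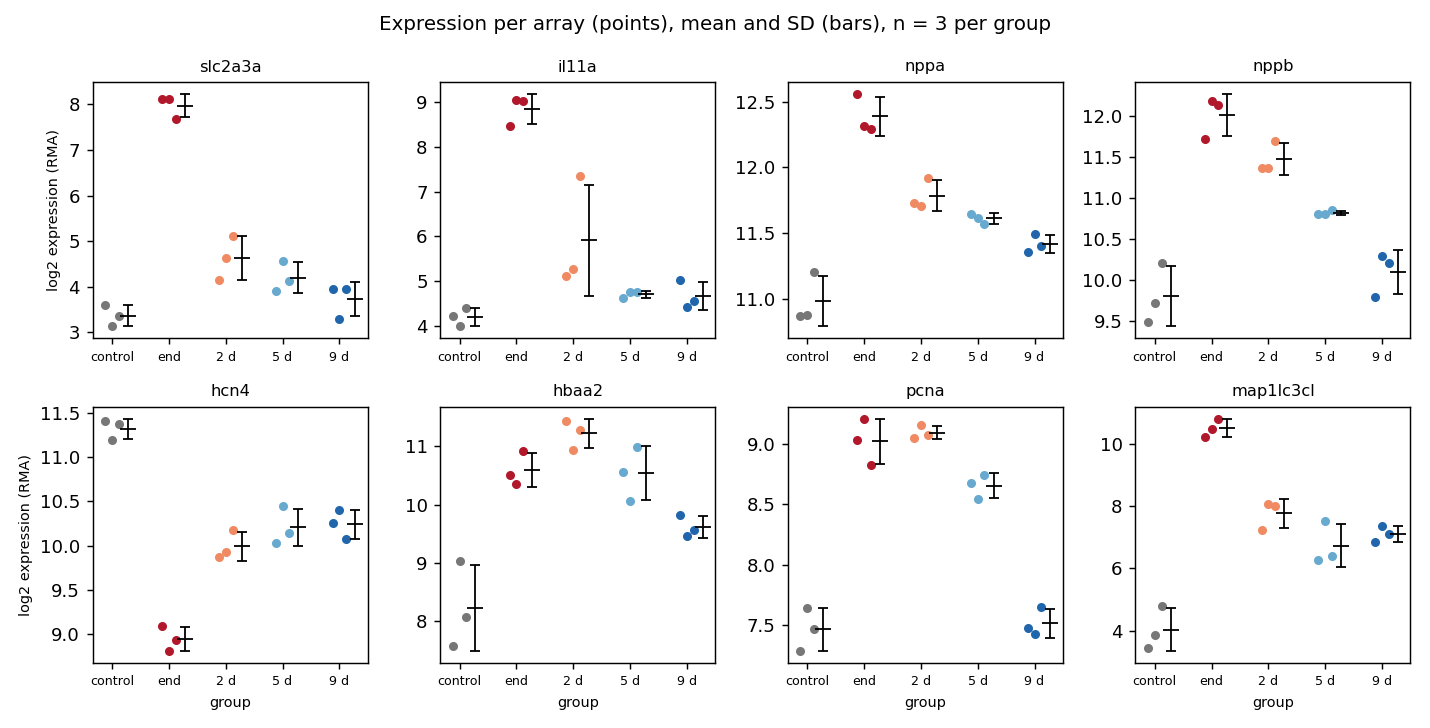
Log2 expression (RMA) of 8 genes on each array (points) with mean and SD (bars), n = 3 per group. Mean slc2a3a was 3.36 in control, 7.98 at the end of treatment and 3.73 at 9 days, and mean hbaa2 was 8.23, 10.59 and 9.62.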

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

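The comparisons with other splits of the arrays were set before the results were seen. The tests on list scores and clock genes were chosen only after.

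Other splits of the arrays called few genes. In each of the 9 pairwise comparisons 1 of 10 splits, the real one, gave as many calls, and 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 4669 and 0 for the end of treatment against control, 2268 and 0 for 2 days, 1227 and 3 for 5 days, and 1452 and 1 for 9 days. Against the end of treatment they were 1536 and 1 for 2 days, 2377 and 0 for 5 days, and 3662 and 0 for 9 days. They were 36 and 1 for 5 days against 2 days and 1178 and 0 for 9 days against 5 days, all by limma. For the 5189 genes that differed among the 5 groups, 1 of 100 splits, the real one, gave as many, with a highest other of 808. For the 158 called list tests 1 of 100 did, with a highest other of 145, which lies close to the real total. These shares argue against chance for the totals, but 100 splits cannot exclude it. Within single comparisons, where 10 splits are too few for a share under 0.05, the called lists and the highest of the other splits lay closer. They were 22 and 21 for the end of treatment against control, 23 and 22 for 2 days, 18 and 15 for 5 days and 27 and 15 for 9 days. They were 16 and 14, 14 and 13, and 13 and 16 for 2, 5 and 9 days against the end of treatment, 15 and 14 for 5 days against 2 days and 15 and 13 for 9 days against 5 days, so another split called more lists in 1 comparison. These counts are adjusted over the 33 lists of each comparison.

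Mitosis genes were higher than control at the end of treatment and at 2 and 5 days, with mean scores of 0.93, 0.67 and 0.84, and 0.07 at 9 days. Dividing erythroid cells in the blood of the ventricle are a candidate source. Between 2 and 5 days the mitosis score moved by 0.17 ± 0.06 and the erythroid maturation score by -0.29 ± 0.10, a difference of 0.46 ± 0.11 (SE). The mitosis score thus did not follow the erythroid maturation score in this interval. That list includes red cell and haem synthesis genes such as slc4a1a and urod. Its score need not follow dividing erythroid cells, so the difference cannot decide on them. The mean DNA replication score went with the erythroid one from 2 to 5 days (0.70 to 0.45 beside 0.84 to 0.55), but not from the end of treatment to 2 days (0.69 to 0.70 beside 0.46 to 0.84) or at 9 days (-0.04 beside 0.28), and its source was not tested. More leukocytes are another candidate, but between 5 and 9 days the mitosis score moved by -0.76 ± 0.06 and the pan leukocyte score by -0.02 ± 0.10, a difference of -0.74 ± 0.13, which argues against their number alone. Immature erythroid progenitors, dividing leukocytes and division of heart cells stay open, and none of them was tested.

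Sarcomere genes were lower at the end of treatment, with a score change of -0.26 ± 0.04 (SE), while several cell type lists were higher. A loss of cardiomyocytes alone could give both and would raise the markers of every other cell type alike. Of 10 cell type lists, those for pan leukocyte and epicardium had the highest and lowest changes, a pair picked out of 45 after the scores were seen. The pan leukocyte score changed by 1.00 ± 0.10 and the epicardium score by -0.18 ± 0.10. The difference was 1.17 ± 0.13 (9.22 standard errors, and past the test after correction for all 45 pairs). Where scores follow cell shares, this argues against a loss of cardiomyocytes alone as the whole explanation. A gain of other cells, unequal between types, would also lower the share of cardiomyocytes, and the comparison cannot decide on that. The epicardium genes went both ways, such as anxa2a (1.31 ± 0.21) and podxl (-0.50 ± 0.07), so their score may not follow the share of epicardial cells. A change in the cell types whose markers rose, and lower expression within cardiomyocytes, stay open.

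Clock genes were tested because arrays of a group may have been taken at another time of day. At the end of treatment clock and bmal genes changed by a median of 0.36 ± 0.13 (SE) and dbp, tef, nr1d, per1a, per1b and per3 genes, of the opposite phase, by -0.44 ± 0.09, a difference of 0.80. The gene per2, which rose by 1.85 ± 0.17, was left out of that set, and the difference was not computed with it. Examples were clocka (0.79 ± 0.13), bmal1b (0.83 ± 0.18), dbpb (-1.05 ± 0.13) and tefb (-0.86 ± 0.10), while tefa (0.74 ± 0.10) and nr1d4a (0.42 ± 0.14) went the other way and others, such as clockb (0.05 ± 0.09) and npas2 (-0.07 ± 0.17), did not pass the test. Time of day and treatment cannot be told apart here, because the sources used give no sampling time and it could differ by group.

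Some genes were called on opposite sides of control at different times, and limma called the difference between those times. From the end of treatment to 2 days bag3, a chaperone partner, differed by 0.82, nfe2, a blood cell transcription factor gene, by 1.14, and stat2 by 1.05, each from below control to above it. From the end of treatment to 5 days klf11b differed by -3.19, from 1.59 ± 0.21 above control to below it, and by 2.49 from 5 to 9 days. The stress gene ddit3 differed by -0.88 from the end of treatment to 5 days, but its call against control at 5 days was lost without control replicate 3 (adjusted p = 0.0866) and without 5 days after treatment replicate 1 or 2 (0.0899 and 0.0504).

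From the end of treatment to 9 days the lists for DNA replication, glycolysis and proteasome had median differences of -0.79, -0.54 and -0.46, and DNA replication differed by -0.47 from 5 to 9 days. At the preset correlation the lists were called above control at the end of treatment and below it at 9 days. None of the 3 calls at 9 days held with an estimated correlation (adjusted p = 0.474, 0.392 and 0.11), and at the end of treatment that of DNA replication held (adjusted p = 0.0238) and those of glycolysis and proteasome did not (0.0722 and 0.158). The mean DNA replication score at 9 days was -0.04 ± 0.03 (SD, n = 3), against -0.01 ± 0.01 in control. At the preset correlation DNA replication at 9 days lost its call without control replicate 2 or 3 (adjusted p = 0.108 and 0.0532) and without 9 days after treatment replicate 2 (0.124), and that of glycolysis without control replicate 2 (0.168) and 9 days after treatment replicate 1 (0.111). Among genes called above control at the end of treatment and below it at 9 days, rpa2 differed by -1.20 from the end of treatment to 9 days and by -1.25 from 5 to 9 days, lig1 by -1.04, pfkpb by -0.72, pgam1a by -1.52, gpia by -0.90, psmd2 by -0.51, psmd12 by -0.77, acta2 by -1.56, ldha by -0.74 and tfr1b, a transferrin receptor gene, by -1.76. The Z-disc gene ldb3b differed by 0.57, from below control to above it. The call against control at 9 days was lost for rpa2 without control replicate 3 (adjusted p = 0.0524). It was lost for lig1 without control replicate 1 or 3 (0.121 and 0.0727) and each 9 days after treatment replicate (0.0505, 0.0903 and 0.0725). For pgam1a it was lost without control replicate 1 or 2 (0.0558 and 0.0943) and 9 days after treatment replicate 2 (0.0804). For gpia it was lost without control replicate 1 or 2 (0.0586 and 0.102) and each 9 days after treatment replicate (0.0729, 0.054 and 0.0565). For acta2 it was lost without control replicate 1 or 3 (0.062 and 0.14) and each 9 days after treatment replicate (0.0551, 0.136 and 0.0872).

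Transcript clusters outside the main test also differed between the end of treatment and control. Of 53551 clusters without a gene name here 3180 were called, 1432 higher and 1748 lower, and of 855 clusters with several symbols 140 were called, 94 higher and 46 lower.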

How the results depend on the processing

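The blood score covariate was added after seeing the data, and the other alternatives were planned. Counts of called genes stayed within 1.5 times with a robust variance, array weights, array centring, cyclic loess, the replicate block, the mean of a gene's clusters, and the third of genes with the lowest mean left out (12840 genes tested). With array centring or cyclic loess the median change of all genes lay within 0.0529 of 0 in each comparison. Replicate numbers did not pair the arrays: 0 of the 10 array pairs of each number had a correlation over 0.1 after group means were removed. With the block 161 list tests were called, and with fry's directional test 143. Over the named genes in all 9 comparisons, called or not, leaving out 1 array left 6914 results with the same sign and on the same side of the threshold, ended 625 calls, brought 69 and turned the sign of 60 uncalled values, and by limma 0 called values turned sign.

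A 1.5-fold minimum lowered the counts by construction, to 2305, 1028, 567 and 568 against control at the end of treatment, 2, 5 and 9 days, to 754, 1079 and 1634 against the end of treatment, and to 485 for 9 days against 5 days. Shared calls in the same direction became 783, 463 and 342 for the end of treatment with 2, 5 and 9 days, 447 and 250 for 2 days with 5 and 9 days, and 177 for 5 with 9 days. Genes moved back at 2, 5 and 9 days became 557, 868 and 1141, and those still called 783, 463 and 342. Testing every transcript cluster gave 7042 calls for the end of treatment against control and 5 for 5 days against 2 days. Without the variance trend the latter count was 15, and the cause was not tested. With only the 6 arrays compared, fewer arrays inform the variance, and the counts were 777 for 5 days against control and 636 for 9 days against 5 days. Leaving out 1 array gave 1469 to 1872 calls for 2 days against control, 755 to 1068 for 5 days and 713 to 1245 for 9 days, and 984 to 1304 for 2 days against the end of treatment. It gave 8 to 29 for 5 days against 2 days and 615 to 1172 for 9 days against 5 days. For the end of treatment against control it gave 3878 to 4129. An estimated correlation lowered the called list tests to 32, and fry's mixed test, which asks for change in either direction, called 254.

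With the blood score as a covariate the counts were 1963, 0, 9 and 439 against control at the end of treatment, 2, 5 and 9 days, 514 for 2 days against the end of treatment, 3 for 5 days against 2 days and 344 for 9 days against 5 days, by limma. Group explained 86.6% of the score and, at equal residual variance, standard errors were multiplied by 1.03 to 2.6. Lost calls therefore do not show that blood was the source. At 2 days against control 1512 genes had an unadjusted p under 0.05. Under this covariate the sign turned for some lists and genes, and the cause was not tested. At 2 days against control medians became -0.15 for apoptosis and p53, -0.26 for circadian clock, -0.004 for hypoxia response, -0.30 for neutrophil, -0.11 for proteasome and 0.14 for skeletal muscle genes. The same fit gave -0.14 for sesn2, -0.13 for fibinb, -0.081 for socs3b, 0.22 for pvalb4 and -0.022 for ogdhb. At 5 days against control medians became -0.115 for glycolysis, -0.01 for oxidative stress, haem and iron, and 0.12 for skeletal muscle, and at 9 days -0.068 for cytosolic ribosome. The mean of all clusters turned myh7 at the end of treatment to -0.55, and the cause was not tested. Without 5 days after treatment replicate 3 the fatty acid oxidation median between 2 and 5 days was -0.101 and the list was called lower (adjusted p = 0.0393), against 0.004 and no call with all arrays (adjusted p = 0.951) and up to 0.064 without 5 days after treatment replicate 1. Values carry no detection call, so how far a dim gene lies over background is unknown.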

Other observations

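Values below are log2 differences ± SE by limma, n = 3 arrays per group, for lists that the comparisons above do not describe. At the end of treatment 15 of 38 circadian clock genes rose and 7 fell (17 and 11 adjusted over the list alone), among them cry5 (2.54 ± 0.17) and per2 (1.85 ± 0.17), and the list was not called. Of 40 apoptosis and p53 genes 8 rose and 2 fell, the same adjusted over the list alone, with the death receptor gene fas at 1.55 ± 0.16, and the list was not called. Immediate early genes rose in 10 and fell in 8 of 39 (11 and 8 adjusted over the list alone), with klf4 at -1.36 ± 0.17, jun at -0.70 ± 0.10 and cebpb at 1.21 ± 0.17. That list's median was 0.03 and its test pointed down without a call. Of 52 heat shock and unfolded protein response genes 15 rose and 9 fell (16 and 13 adjusted over the list alone), with the protein disulfide isomerase gene pdia4 at 0.87 ± 0.09 and the heat shock factor gene hsf1 at -0.55 ± 0.07, and the list was not called. Of 67 cytosolic ribosome genes 1 rose and 0 fell by limma (0 and 0 adjusted over the list alone), and of 30 liver plasma protein genes 2 fell (1 adjusted over the list alone), with rbp4 at -1.36 ± 0.12 and adjusted p = 0.338 with an estimated correlation. The liver list lost its call at the preset correlation without control replicate 2 (adjusted p = 0.0963) and without end of treatment replicate 1 (0.0696). The haemoglobin list, with 6 of its 18 genes measured, was not called, although hbaa2 and hbba2 rose.

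Some chaperone genes changed after the end of treatment. From the end of treatment to 2 days 13 of 52 heat shock and unfolded protein response genes rose and 2 fell (16 and 6 adjusted over the list alone), with hspa1b at 1.73 ± 0.30 and ahsa1b at 0.72 ± 0.13 (adjusted p = 0.471 with an estimated correlation). From 5 to 9 days 3 rose and 9 fell (3 and 11 adjusted over the list alone), with the mitochondrial chaperone gene hspd1 at -1.06 ± 0.16 and the endoplasmic reticulum chaperone gene hspa5 at -0.63 ± 0.10 (adjusted p = 0.427 with an estimated correlation). The latter list call was lost without 5 days after treatment replicate 3 (adjusted p = 0.0598). Interferon response genes rose in 8 of 42 at 9 days against control (12 adjusted over the list alone), with isg15 at 1.22 ± 0.20 and dhx58 at 0.95 ± 0.15 (adjusted p = 0.163 with an estimated correlation). Smooth muscle genes fell in 3 and rose in 1 of 22 at 9 days against control (6 and 1 adjusted over the list alone), with myh11a at -0.85 ± 0.15 and rgs5b at 0.90 ± 0.20 (adjusted p = 0.163 with an estimated correlation). Of 14 thrombocyte genes 3 fell from 5 to 9 days (4 adjusted over the list alone), with gfi1b at -0.62 ± 0.10 (adjusted p = 0.187 with an estimated correlation).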
